A study of Trichoderma reesei with 4 samples.

How the data were processed

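The samples were a mycelium control (0 h) and sporulating cultures at 3, 6 and 9 h of Trichoderma reesei QM9414, each represented by 1 GEO sample that stands for 2 biological replicas, per the series' design text. Total RNA was labelled with Cy3 and hybridised to a NimbleGen 1-colour array of the predicted genes, per the labels' protocols. Per the file headers and the submitters' processing notes, the authors deposited log2 expression values obtained with RMA, which corrects background, quantile normalizes arrays and summarises probes. The version of RMA is not given in the sources used here, nor is the genome build of the array. Per the file headers, the deposited table of 9126 features holds a mean log2 value and an SD for each of the 4 times and 1 p-value per feature. RMA makes the distributions of all arrays alike, so a change in total RNA per cell cannot be seen in these values, and bright features are compressed towards the upper end of the scale.

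What the deposited SD and p-value are was settled from the values. A one-way analysis of variance over the 4 times was computed from the means and SDs for 2 replicas and adjusted by the Benjamini-Hochberg method over all 9126 features. It gave the authors' p-value within 1% for 9015 features, or 98.78%. Assuming 3 replicas it did so for 14 features and assuming 4 replicas for 5. The SD is therefore taken as the sample SD of 2 replicas. A second deposited table of log2 values held the same means, with a largest difference of 0. Values of single arrays were not analysed here.

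The design fixed before the data were examined foresaw either columns of separate replicas, to be tested with limma, or single values, with no test. The table held means and SDs instead. From the means, the SDs and 2 replicas per time, limma's residual variance of each feature follows exactly, with 4 residual degrees of freedom, and its moderated test (contrasts.fit and eBayes, prior degrees of freedom 3.82, prior variance 0.015) was run on that. All 4 times were in 1 fit with no covariates. Features were called with an adjusted p under 0.05 and a change of at least 2-fold, a log2 change of 1. A feature counted as changed at any time by the moderated F test over the 3 comparisons with 0 h, with adjusted p under 0.05. It also needed a change of at least 2-fold against 0 h at 1 time or more, with no pairwise p required. Standard errors of log2 changes had a median of 0.12.

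The computation was tested on simulated data for the comparison of 3 h with 0 h, with 8 arrays of 9126 features drawn from the real means and SDs. The test from summaries and limma's fit to the arrays gave the same statistics within 5.97e-13. Of 100 features changed by a log2 value of 1, 78 passed the adjusted p and 39 passed both thresholds, since a true 2-fold change is measured under 2-fold about as often as over it. Of 100 changed by a log2 value of 2, 98 passed both, and 4 unchanged features were called. The list test, on 9000 simulated independent genes, called the 1 changed list of 20 genes and 0 of 20 random lists. This simulation does not show how the test fares with correlated genes.

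Gene names come from the RefSeq table of the T. reesei QM6a assembly v2.0. Of 9122 TRIRE2 identifiers, 9094 were listed there and 28 were not, 235 had a symbol, and 4 features carried other names. The table gives symbols and no product names, so 34 of the 35 product-name patterns fixed before the data were examined matched nothing. Of 44 identifiers fixed in advance with an expected name, 24 had that symbol in the table, and the other 20 are not named. Values of some single genes are not reported here. Lists of cellulases, beta-glucosidases, hemicellulases, cellulase regulators and hydrophobins are therefore partial. The ribosomal protein, proteasome, chitin degradation, histone, secretory pathway, small GTPase, light response, signalling and metabolism lists were put together from the symbols after the files had been opened and before most of their values were seen. No list of conidiation or pigment genes could be filled. Lists with 5 or more members were tested with camera (cameraPR, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over lists and times. A correlation between genes could not be estimated, because that needs values of single arrays, so no list call could be checked that way.

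Genes were named by a rule fixed before the data were examined. It takes members of the lists given by identifier, the 3 largest rises and falls of each list, and, in each comparison, the 10 largest rises and falls among features above the 25th percentile of mean level (9.63) whose replicas do not overlap between the 2 times. With 2 replicas the values follow from the mean and SD, so that last condition could be tested. Genes without a symbol are named by identifier, at most 2 in each direction. Genes of the lists made from symbols fall outside the rule, as do others said below to be chosen after their values were seen.

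As a measure of background, 3 added features named for the MAT1-1 mating type were used, since the QM6a lineage carries the other mating type. Their means lay between 4.0 and 5.53, and 477 features (5.23%) had all 4 means at or under 5.53. That upper limit rests on 1 of the features, as the means of the other 2 did not exceed 4.23. The means of 178 features exceeded 15 at some time. Alternatives tried were quantile normalization and median centring of the 4 mean columns with the SDs as deposited, a filter on low mean level, fold thresholds of 4 and 1.5, a prior that follows the mean level, a fit of only the 2 times compared, and list tests without genes of more than 1 list. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.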

Results

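Gene expression was measured in the filamentous ascomycete Trichoderma reesei as it passed from mycelial growth to the formation of conidia, its asexual spores. The strain, QM9414, is an early mutant of the cellulase-producing lineage of this fungus. Cultures grew on malt extract agar covered with cellophane, and total RNA was labelled with Cy3 and hybridised to a 1-colour gene array. There were 4 groups, a mycelium control at 0 h and sporulating cultures at 3, 6 and 9 h, with 2 biological replicas each. No culture without sporulation was sampled at 3, 6 or 9 h. Changes due to sporulation therefore cannot be told apart from those due to time in culture. The deposited table gives, for 9126 features and each time, the mean log2 expression of the 2 replicas and their SD, and these means ± SD (n = 2) are the levels printed here. The median level over all features was 11.56 at 0 h, 11.53 at 3 h, 11.55 at 6 h and 11.56 at 9 h. The median SD was 0.0981, 0.0992, 0.0898 and 0.0821 on the log2 scale at these times. The number of arrays, 2 per time, limits the precision of every value.

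The submitters followed conidiation by a marker enzyme, and the expression of its gene and of the hydrophobin genes was examined first. Expression of lxr1, which encodes a D-mannitol dehydrogenase, was 11.96 ± 0.2 at 0 h, 13.33 ± 0.12 at 3 h, 13.94 ± 0.14 at 6 h and 13.89 ± 0.12 at 9 h. It was 2.58-fold higher at 3 h than at 0 h (adjusted p = 1.40e-04), 3.93-fold higher at 6 h (adjusted p = 2.33e-05) and 3.8-fold higher at 9 h (adjusted p = 1.86e-05). These and all other adjusted p-values of single genes come from limma's moderated test with Benjamini-Hochberg adjustment. Those of whole gene lists come from camera, adjusted over lists and times. The hydrophobins are small secreted proteins that coat fungal surfaces, and 2 of the 3 that could be named, hfb2 and hfb3, rose at every sampled time. The level of hfb3 was 9.63 ± 0.55 at 0 h and 14.15 ± 0.025 at 3 h, a 22.9-fold rise (adjusted p = 3.73e-06), and hfb2 rose 8.56-fold at 3 h (adjusted p = 1.47e-05). The third, hfb1, stayed between 7.72 and 8.22, and its changes against 0 h did not pass the test.

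The comparison of 3 h with 0 h asks what changes at the first sampled time of sporulation. Genes of the cellulase and hemicellulase lists showed the largest rises among the genes with a symbol. Of the 9 genes in the cellulase list, 8 rose, with a median log2 change of 7.39 over the list. The gene cip2, which encodes a glucuronoyl esterase, rose by 8.95 log2 units, from 5.04 ± 0.019 to 13.99 ± 0.08, and the cellulose-binding protein gene cip1 by 8.21. The endoglucanase genes cel5a, cel12a and cel7b rose by 8.07, 7.39 and 5.1 log2 units. The cellobiohydrolase gene cel7a rose 16.5-fold, from 11.46 ± 0.17 to 15.5 ± 0.072, which lies near the upper end of the scale at 16. The lytic polysaccharide monooxygenase genes cel61a and cel61b rose by 5.43 and 7.46 log2 units. The remaining member, cel5b, was already at 13.47 ± 0.018 at 0 h, and its change of 0.31 did not pass the test. The 0 h level of cip2 lay within the range of 4.0 to 5.53 shown by 3 mating-type features that the strain is not expected to carry, so its changes against 0 h rest on a background-level control value and their sizes are not exact.

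Of the 5 beta-glucosidase genes, which act on cellobiose, 4 rose at 3 h. The largest rise was that of cel3a, at 29.8-fold (adjusted p = 1.11e-06), followed by cel3c at 2.58 log2 units, cel1a at 2.31 and cel1b at 1.2. The change of cel3b was 0.05 and did not pass. Both genes of the hemicellulase list rose, the acetyl xylan esterase gene axe1 by 8.34 log2 units and the mannanase gene man5a by 4.08. Another acetyl xylan esterase gene with a symbol, axe2, lay outside that list, and its change of 0.31 stayed under 2-fold. Among the regulators of cellulase genes, xyr1, the main activator of cellulase and xylanase genes, rose 2.15-fold (adjusted p = 7.15e-05). Changes of cre1 and ace1 at 3 h were 0.42 and 0.02 and stayed under 2-fold. Camera, which sets a list against all other genes, gave adjusted p = 6.79e-62 for the cellulases and 5.02e-06 for the beta-glucosidases. Counts adjusted over the list alone were the same, 8 of 9 and 4 of 5.

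Ribosomal protein genes went the other way at 3 h. All 42 named members had a negative change, with a median of -0.76 on the log2 scale, and 10 of them passed both thresholds, rpl15 at -1.27, rpl5 and rps12 at -1.26, and rps9 at -1.19 being the lowest. Adjusted over the list alone the count was 10 as well, and camera gave adjusted p = 8.96e-08. With median centring, rpl28 and rps14 were among those that ended just short of 2-fold. The serine protease gene prb1 fell by 2.88 log2 units, from 12.67 ± 0.3 to 9.79 ± 0.14. The superoxide dismutase gene sod1 rose by 3.91 log2 units, from 10.04 ± 0.47 to 13.95 ± 0.084 (adjusted p = 1.50e-05). The light-response regulator gene env1 rose 2.73-fold. The gene with the symbol phr1 in the gene table, TRIRE2_107680, rose 2.78-fold, but another identifier had been fixed in advance for the photolyase gene phr1, so its identity is in doubt at every time. The differences of the photoreceptor genes blr1 and blr2 were 0.51 and 0.13 and did not reach 2-fold. The D-xylose reductase gene xyl1 rose by 1.24 log2 units. Among 20 genes of chitin degradation 3 rose and 2 fell, and the list as a whole did not stand apart (adjusted p = 0.918). Its rising members were chi18-8 at 1.94, chi18-rel1 at 1.63 and chit18-11 at 1.07, and its falling members were chi18-17 at -1.38 and chi18-14 at -1.16. The 0 h level of chi18-8 and the 3 h levels of chi18-14 and chi18-17 lay within the background range, so the sizes of these 3 changes are not exact. Of the genes without a symbol, TRIRE2_120229 rose by 6.99 log2 units and TRIRE2_80879 fell by 5.93.

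In all, 618 features were higher and 438 lower at 3 h than at 0 h, with adjusted p under 0.05 and a change of at least 2-fold. By adjusted p alone 3999 features differed, 1822 higher and 2177 lower, so the balance of directions depends on the fold threshold. At a 4-fold threshold the counts were 187 higher and 85 lower. Leaving out features under the 25th percentile of mean level, about 9.63, gave 422 higher and 290 lower.

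**Figure D1:**
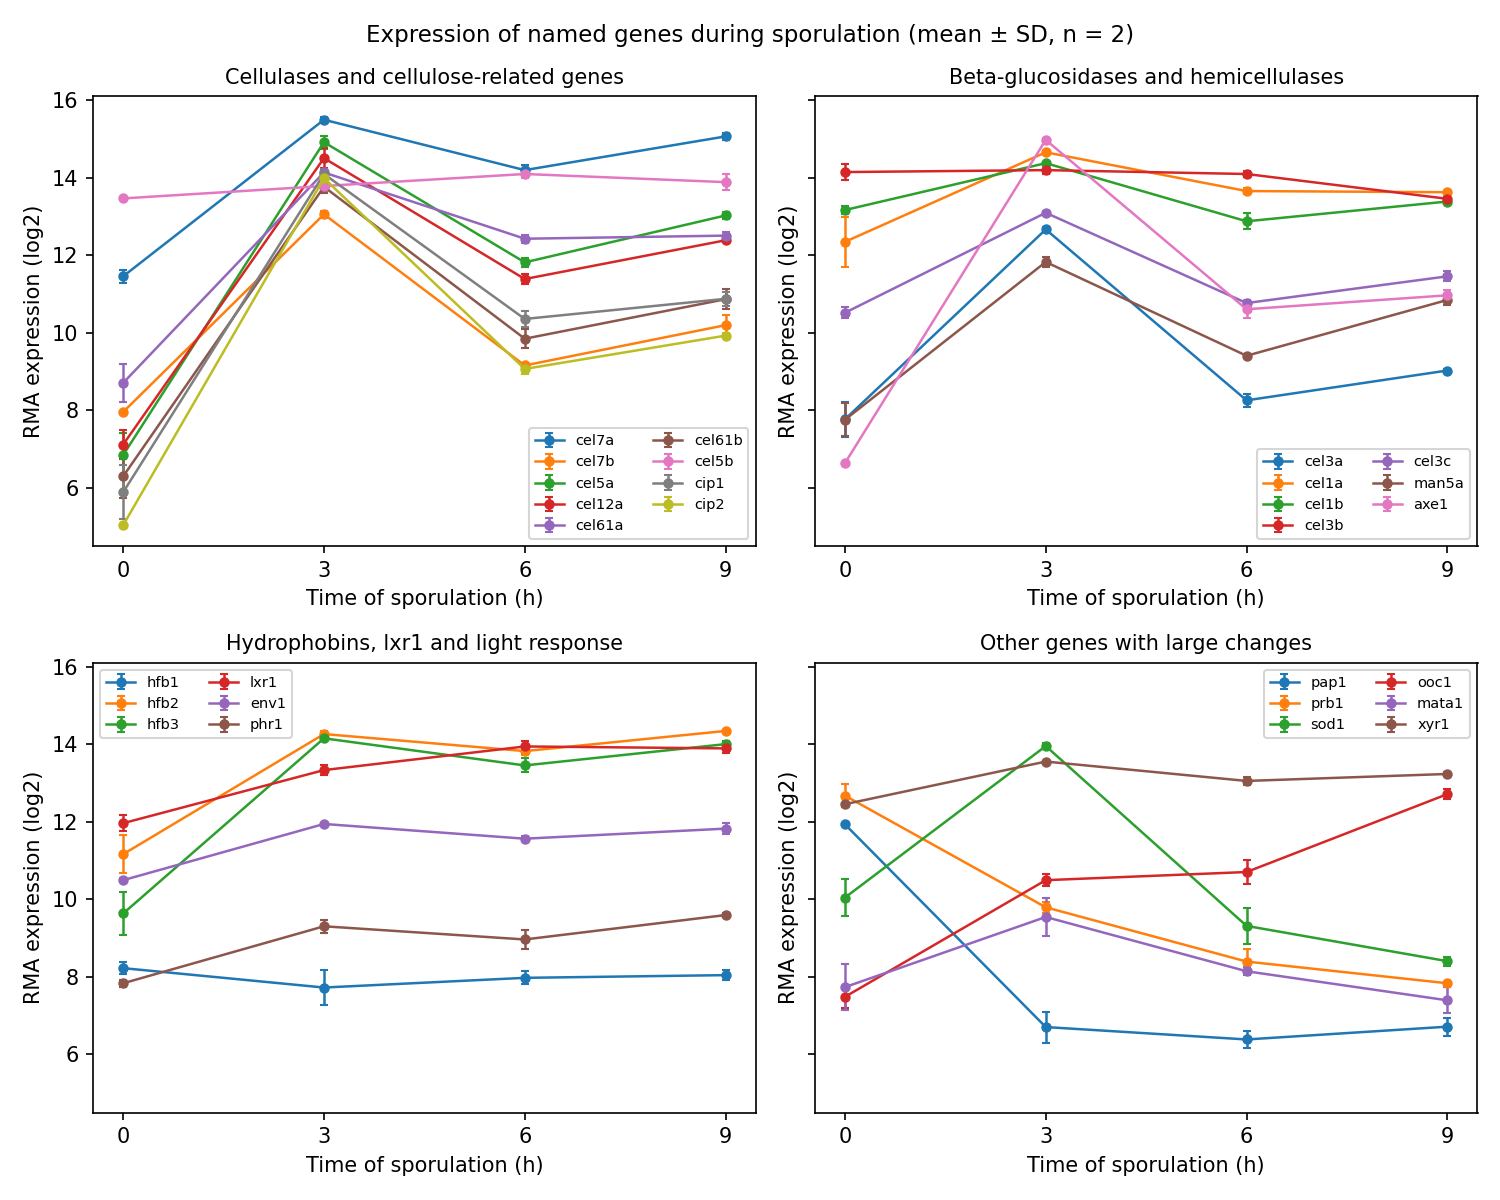
Log2 expression after RMA (vertical axis) against hours of sporulation (horizontal axis) for named genes in 4 panels. Points are the authors' means, bars the deposited SD of 2 replicas, and lines join the means. Nearly all cellulase genes peak at 3 h, with cip2 going from 5.04 at 0 h to 13.99 at 3 h and 9.07 at 6 h, while hfb2, hfb3 and lxr1 stay high to 9 h.

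The comparison of 6 h with 0 h asks which differences from mycelium are found at the middle time. The same 8 of 9 cellulase genes were higher than in mycelium, with smaller changes and a list median of 3.72. The gene cel5a was 4.97 log2 units above its 0 h level, cip1 4.47 and cel12a 4.26. The level of cip2, at background at 0 h, was 9.07 ± 0.14. The level of cel7a was 14.2 ± 0.13, 6.69-fold above mycelium, and cel7b was 2.3-fold above. Of the beta-glucosidase genes, 1 of 5 was higher, cel1a at 1.32, and cel3a, at 8.26 ± 0.17, did not pass the test (adjusted p = 0.0796). Both axe1, at 3.97, and man5a, at 1.66, were higher. Hydrophobin genes hfb3 and hfb2 were 14.2-fold and 6.31-fold above mycelium, and env1 and the table's phr1 were 2.1-fold and 2.19-fold above.

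Camera at 6 h gave adjusted p = 3.27e-20 for the cellulases and 0.918 for the beta-glucosidases. None of the 42 ribosomal protein genes passed both thresholds, although 41 had a negative change and the list stood below the other genes, with a median of -0.31 (adjusted p = 0.0243). Like every camera call here, this one rests on the preset inter-gene correlation of 0.01, which could not be checked. A higher correlation among these genes would weaken it. The gene prb1 was 19.5-fold below its mycelium level. Without a symbol, TRIRE2_106538 rose by 6.02 log2 units and TRIRE2_112567 fell by 6.83, from 14.1 ± 0.024 to 7.27 ± 0.01. The counts were 610 higher and 390 lower, or 169 and 95 at 4-fold, and by adjusted p alone 1825 and 1770. With features of low mean level left out they were 393 and 188.

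The comparison of 9 h with 0 h asks the same of the last sampled time. Cellulase genes stood above mycelium in 8 of 9 cases, with a list median of 4.57 (camera adjusted p = 1.73e-23). The gene cel5a was 72.2-fold above mycelium (adjusted p = 8.93e-07), cel12a 38.5-fold, cip1 31.7-fold and cel7a 12.3-fold. Of the beta-glucosidase genes, cel1a at 1.28 and cel3a at 1.26 were higher. By adjusted p alone, cel3c was higher at 0.94 (adjusted p = 3.47e-04) and cel3b lower at -0.69 (adjusted p = 0.00261). The list did not stand apart (camera adjusted p = 0.648). The level of axe1 was 4.33 log2 units and that of man5a 3.1 above mycelium. Hydrophobin genes hfb3 and hfb2 were 20.8-fold and 9.08-fold above, env1 2.52-fold and the table's phr1 3.4-fold. The gene ooc1 reached 12.71 ± 0.12 from 7.48 ± 0.28 at 0 h, a 37.5-fold rise.

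Among genes that were lower at 9 h, prb1 had fallen by 4.85 log2 units, to 7.83 ± 0.019. The gene sod1, high at 3 h, was at 8.4 ± 0.12, 3.12-fold below mycelium (adjusted p = 0.00131). Of 8 proteasome and ubiquitin genes 1 fell, psa7 at -1.1, and the list median was -0.6 (camera adjusted p = 0.077). None of the 42 ribosomal protein genes passed both thresholds, and all 42 changes were negative with a median of -0.33. Their camera test passed with the values as deposited (adjusted p = 0.0375) and missed after quantile normalization (adjusted p = 0.057). Histone genes, small GTPase genes and genes of the secretory pathway gave no camera call at any time. Of the genes without a symbol, TRIRE2_76230 rose by 8.18 log2 units, from 6.47 ± 0.25 to 14.65 ± 0.51, and TRIRE2_112567 fell by 8.02. The counts at 9 h were 683 higher and 493 lower. By adjusted p alone they were 2069 and 2288, at 4-fold 223 and 117, and without features of low mean level 454 and 328.

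**Figure D2:**
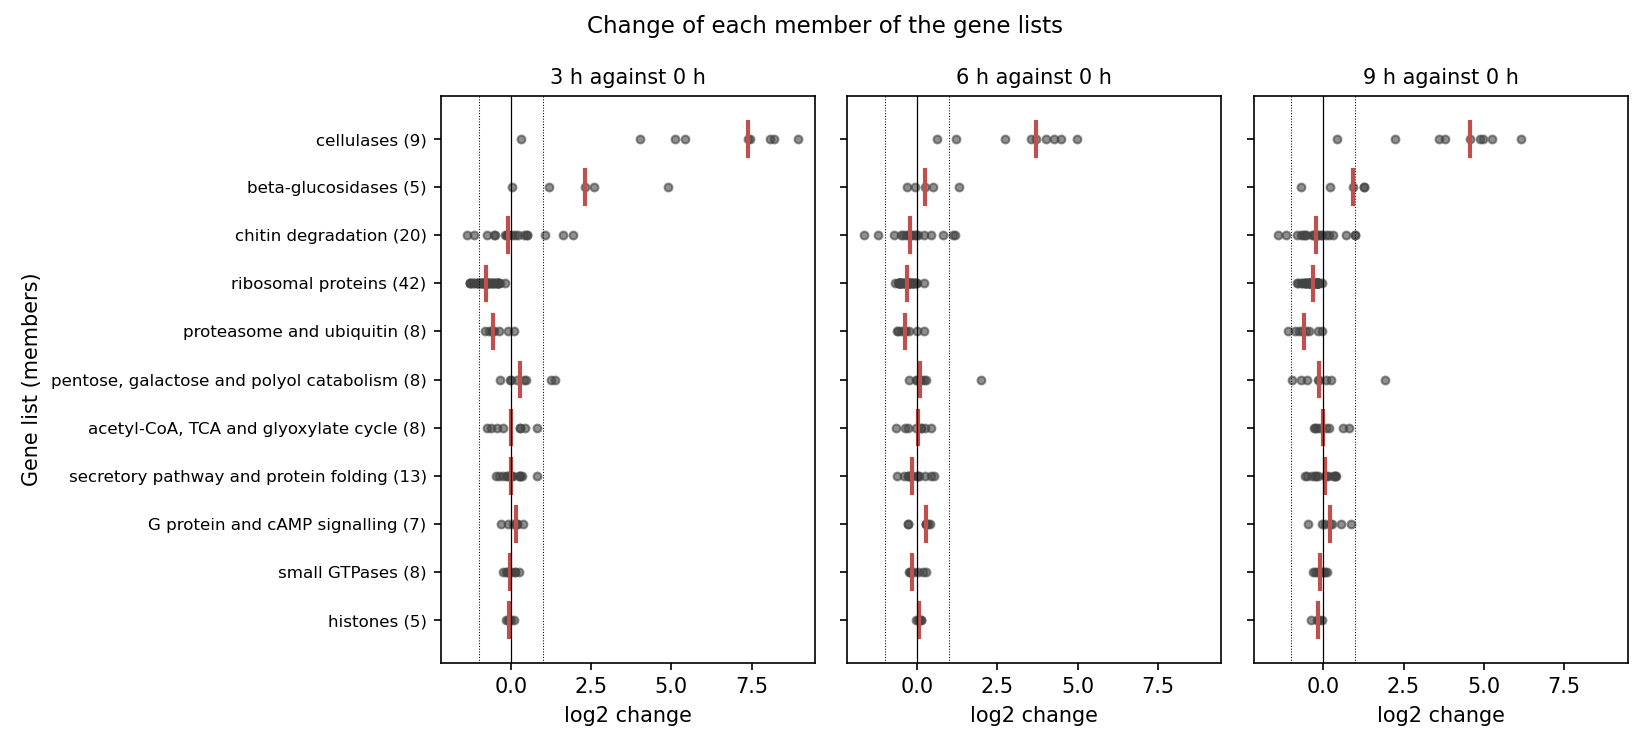
Log2 change against 0 h (horizontal axis) of each member of 11 gene lists (vertical axis, number of members in brackets) at 3, 6 and 9 h. Dots are genes, red bars the list medians, and dotted lines mark 2-fold. The cellulase median is 7.39 at 3 h, 3.72 at 6 h and 4.57 at 9 h, and the ribosomal protein median is -0.76, -0.31 and -0.33.

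The comparison of 6 h with 3 h asks what changed between the first and middle times of sporulation. Of the 16 named cellulase, beta-glucosidase and hemicellulase genes, 13 fell and 0 rose, with a median change of -2.76. The log2 change was -4.92 for cip2, -4.41 for cel3a, -4.37 for axe1, -3.91 for cel61b and -3.9 for cel7b, while cel7a fell 2.46-fold. The gene sod1 fell 24.9-fold, from 13.95 ± 0.084 to 9.31 ± 0.46 (adjusted p = 2.51e-05). The protein disulfide isomerase gene pdi1 fell by 1.05 log2 units. Changes of hfb2, hfb3 and lxr1 between these times were -0.44, -0.69 and 0.61 and did not reach 2-fold. Ribosomal protein genes had positive changes in 42 of 42 cases, with a median of 0.45, and 1 of them, rla0, passed both thresholds. Of the genes without a symbol, TRIRE2_43701 rose by 4.17 log2 units and TRIRE2_120229 fell by 4.95. The counts were 217 higher and 239 lower, or 23 and 61 at 4-fold. By adjusted p alone they were 1117 and 868, and without features of low mean level 102 and 117.

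From 6 h to 9 h 5 of the 16 genes rose again and 0 fell. These were man5a at 1.44, cel5a at 1.21, cel7b at 1.04, cel61b at 1.02 and cel12a at 1.0, the last ending just short of 2-fold after quantile normalization. The change of cel7a was 0.87 and did not reach 2-fold. The gene ooc1 rose 4.01-fold (adjusted p = 0.00133). Neither the hydrophobin genes nor lxr1 passed the test, with changes of 0.53 for hfb2, 0.55 for hfb3 and -0.05 for lxr1. Of the genes without a symbol, TRIRE2_58717 rose 11.7-fold and TRIRE2_55062 fell by 1.77 log2 units. This was the step with the fewest calls, 102 higher and 74 lower. At 4-fold 20 were higher and 0 lower, where by adjusted p alone 486 were higher and 728 lower. Without features of low mean level the counts were 38 and 35.

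**Figure D3:**
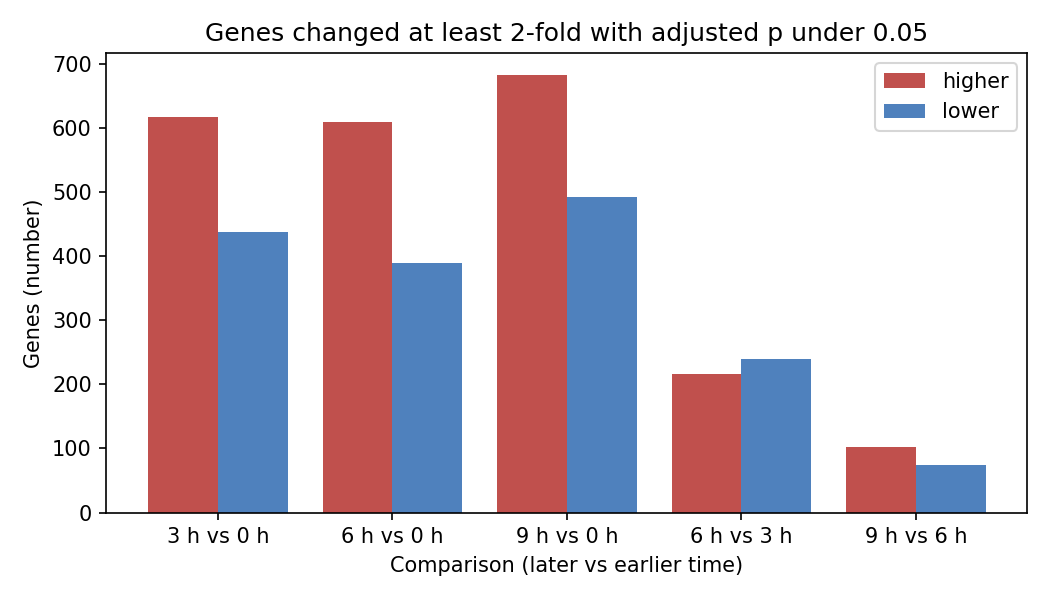
Number of features (vertical axis) that were higher (red) or lower (blue) in each comparison of a later with an earlier time (horizontal axis), at adjusted p under 0.05 and at least 2-fold. Comparisons with 0 h give 618, 610 and 683 higher features, and the step from 6 h to 9 h gives 102.

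Over all times, 1727 features differed from 0 h by the moderated F test with a 2-fold change at 1 time or more. Of these, 680 had their highest mean at 0 h, 398 at 3 h, 209 at 6 h and 440 at 9 h. At all 3 sampled times 344 features were higher, among them cel5a, cip1, hfb2, hfb3 and lxr1, and 194 were lower, prb1 among them. The lists of 3 h and 6 h shared 402 higher features, where independent lists of these sizes would share 41.3, and 215 lower ones against 18.7. Those of 6 h and 9 h shared 494 higher features against 45.7, and those of 3 h and 9 h 388 against 46.3. All of these comparisons use the same 0 h arrays, which adds to such overlaps. In 20 simulations of unchanged groups that share a control, at most 2 features were called in any comparison and 0 were shared between comparisons with 0 h. With so few calls the simulated overlaps could hardly differ from 0, so they do not measure the part due to the shared control. Across genes, which are not independent replicates, the log2 changes at 3 h and 9 h had a covariance of 0.554, against 0.0113 in the simulations. Noise in the shared 0 h arrays, at the spread between replicas, thus gave only a small part of this covariance. With 2 arrays per time the controls could not be split, so the part of the shared counts due to the shared control was not measured. Of the 618 features higher at 3 h, 134 fell again by 6 h, cip2, axe1 and cel3a among them. Independent lists would share 16.2. Both comparisons use the 3 h arrays with opposite sign, which adds to this number. The simulations of unchanged groups gave at most 1 such feature over both directions, which again follows from their few calls. Across genes, the covariance of these log2 changes was -0.179, against -0.0113 in the simulations, and Pearson's r was -0.41, against -0.498 in the simulations. In unchanged groups this r follows from sharing the 3 h arrays, whatever the spread, so it cannot measure the part of the reversal due to them. The covariance does depend on the spread. Noise at the spread between replicas gave only a small part of the observed covariance.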

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

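The change of sod1 against 0 h differed between times. It was 3.91 on the log2 scale at 3 h and -1.64 at 9 h, both past the thresholds and of opposite sign, and the difference of -5.55 was tested directly by comparing 9 h with 3 h. Its level was 10.04 ± 0.47 at 0 h, 13.95 ± 0.084 at 3 h, 9.31 ± 0.46 at 6 h and 8.4 ± 0.12 at 9 h. Among all features, 5 were higher at 3 h and lower at 9 h, and 2 were lower at 3 h and higher at 9 h. No explanation was tested.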

How the results depend on the processing

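The authors' p-value, the features of the gene table alone, and the features above the MAT1-1 level were chosen as alternatives after seeing the data. Under these, quantile normalization, median centring, the trended prior and the fit of 2 times, the counts of each comparison stayed within 1.5 times their values. The count at any time was run under quantile normalization, median centring and the authors' p-value and stayed within 1.5 times. At 4-fold the counts higher and lower were 187 and 85 at 3 h, 169 and 95 at 6 h, 223 and 117 at 9 h, 23 and 61 from 3 h to 6 h, 20 and 0 from 6 h to 9 h, and 451 at any time. At 1.5-fold they were 1172 and 1184, 1190 and 915, 1279 and 1290, 610 and 549, and 289 and 389. Without features of low mean level, 6844 were left. The counts were then 422 and 290 at 3 h, 393 and 188 at 6 h, and 454 and 328 at 9 h. They were 102 and 117 from 3 h to 6 h, 38 and 35 from 6 h to 9 h, and 1120 at any time. Each of these counts fell by a larger share than the 25% of features left out, so many calls lay at low mean level. The camera call of the ribosomal proteins at 9 h ended after quantile normalization (adjusted p = 0.057), and the cause was not tested. All other list calls stayed on their side of the threshold under the normalizations, the filter and the removal of shared genes, except that the beta-glucosidases had too few members left to be tested under the filter. Of the calls of single named genes, 4 ended under median centring, 2 under quantile normalization and 1 in the fit of 2 times, and 0 reversed. No paired analysis was possible because the deposited means and SDs do not say which value belongs to which replica. For the same reason leaving out each replica and an estimated inter-gene correlation were not run. The second deposited table holds the same means and no SDs, so it gave no alternative test. Signal limits both ends of the scale, with 477 features at background level and 178 above 15.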

Other observations

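Chosen only after the results were seen were the tests of the features missing from the gene table, and the genes named in this paragraph. The gene pap1 was among the most strongly lowered genes with a symbol, at 11.93 ± 0.021 in mycelium and 6.7 ± 0.4, 6.38 ± 0.23 and 6.71 ± 0.23 at 3, 6 and 9 h. It was 46.9-fold lower at 6 h than at 0 h (adjusted p = 1.02e-06). The gene mata1 was higher at 3 h alone among the 3 sampled times, by 1.8 on the log2 scale (adjusted p = 0.00257). Its SD of 0.6 at 0 h and 0.49 at 3 h was large. The gene cro1 was higher at 6 h and 9 h, by 1.29 and 1.71, nik1 was higher at 9 h by 1.14, and the ergosterol synthesis gene erg28 was lower by 1.05.

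Of the G protein and cAMP signalling genes 0 of 7 passed both thresholds at any time, rgs1 coming closest with a change of 0.85 at 9 h (adjusted p = 0.00169). Of 4 MAP kinase genes, 4 glycolysis genes, 3 glycogen genes, 3 genes of the CCAAT-binding complex, 3 translation factor genes and 2 genes of the mitochondrial ATP synthase, 0 passed both thresholds at any time. Of 8 genes of acetyl-CoA metabolism and the tricarboxylic acid and glyoxylate cycles, 0 passed both thresholds, though by adjusted p alone 4 were higher and 2 lower at 3 h, and camera gave adjusted p = 0.955, 0.955 and 0.918 at 3, 6 and 9 h. In the list of pentose, galactose and polyol catabolism, lxr1 and xyl1 rose at 3 h and lxr1 alone was higher at 6 and 9 h, with camera adjusted p = 0.435, 0.796 and 0.955.

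The named cellulase, beta-glucosidase and hemicellulase genes had their highest mean level at 3 h in 15 of 16 cases. This count includes cel3b, whose 3 h level of 14.2 ± 0.11 hardly differed from its 14.15 ± 0.2 at 0 h. Of the 16 genes, 14 were called higher at 3 h than at 0 h. No explanation for the highest levels at 3 h was tested.

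Genes that changed together tended to lie next to each other in the gene order of the QM6a assembly. There were 126 adjacent pairs of genes both higher at 3 h, against a mean of 41.4 and a maximum of 66 in 10000 shuffled orders (p = 0.0001, the smallest they can give, permutation test), which argues against chance placement. Probes shared within single pairs of tandem copies would confine the excess to adjacent genes, but 181 pairs lay 3 to 5 genes apart against 122 (permutation p = 0.0001). Longer runs of tandem copies could also give such pairs, so shared probes are not excluded. For genes lower at 3 h the adjacent pairs were 55 against 20.9. Those 3 to 5 apart were 73 against 61.5 (permutation p = 0.076), within the range of shuffled orders. For genes lower at 6 h and 9 h the pairs 3 to 5 apart were 69 against 48.7 (permutation p = 0.0023) and 107 against 78.1 (permutation p = 0.0008). Co-regulated clusters may be present as a hypothesis, such as the run of 6 genes from TRIRE2_58701 to TRIRE2_76230, higher at 9 h with a median change of 3.16.

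Features missing from the gene table spread widely between replicas at 9 h. Their median SD was 0.223, where listed features matched on mean level gave a median of 0.0851 and at most 0.162 in 1000 draws (p = 0.001, the smallest they can give, permutation test), which argues against low signal. The draws treat features as independent, but all were measured on the same 2 arrays per time. If the missing features vary together, the p-values in this paragraph are too small. The 7 largest SDs at 9 h, from 1.07 to 2.28, all belong to such features, and those of TRIRE2_34413 correspond to a 9.35-fold distance between the 2 replicas. RNA of another source in some replicas may be the reason, but no sequence was at hand to test where these features come from, so it stays open. At 0 h their median SD was 0.226 (permutation p = 0.002), at 3 h 0.133 (permutation p = 0.27) and at 6 h 0.11 (permutation p = 0.13).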
